A study of Mus musculus with 9 samples.

How the data were processed

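The deposited table holds log2 expression values for 41345 probe sets on 9 single-colour arrays, 1 array per sample and 3 samples in each of 3 groups. Per the submitters' processing notes, the authors made these log2 values with RMA (background correction, normalization across arrays and a summary per probe set) and the oligo package; versions are not given in the sources used here, and neither is whether the normalization covered these 9 arrays alone. Per the labels, 100 nmol of siRNA was given to cells in 12-well plates, the cells were kept growth-arrested for 48 h after confluence, and 250 ng of RNA was labelled with biotin. RMA gives all arrays nearly the same distribution, so a change of most transcripts in one direction would be removed, and it compresses differences of dim probe sets. The array medians (6.47 to 6.56) and the share of values at or above the filter level on each array (49.2% to 51.2%) were close. The values were used as deposited, with no further normalization in the main analysis. Groups and replicate numbers came from the sample titles.

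Genes were named from the platform's annotation table, with symbols compared through gene identifiers with a mouse RefSeq table (GRCm38.p6), which changed 0 symbols. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not named here; the last 2 kinds stayed out of the comparisons. For each of 22180 genes the probe set with the highest mean over the 9 arrays was used (1082 genes had more than 1). A gene was tested where the third highest of its 9 values reached the median of all values in the table, 6.51, which left 12630 genes. Genome positions were not used here.

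Differences were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on all 9 arrays and 1 mean per group, with Benjamini-Hochberg adjustment over the genes tested in each of the 3 comparisons and a threshold of 0.05. All p-values are two-sided. Of the gene lists, 25 were written before the data were examined, with textbook members; 327 of their genes were tested, 62 lay below the filter, 9 were found only on probe sets of several genes and 26 were unnamed here. The 22 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. They cover pro-adipogenic and anti-adipogenic regulators, mature adipocyte genes, glucocorticoid receptor, cAMP and CREB, inflammatory and NF-kB, interferon and p53 targets, S phase and mitosis, extracellular matrix, matrix proteases, cholesterol synthesis, glycolysis, insulin and IGF signalling, Wnt, stress responses, the circadian clock, CD24 partners, reference genes and markers of macrophages and skeletal muscle. The lists of endothelial, epithelial and osteoblast and chondrocyte markers had fewer tested members.

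The genes named in the text were set by a rule written before the data were examined. For IBMX/Dex with scrambled siRNA and for CD24 siRNA against scrambled siRNA they are the 12 largest rises and 12 largest falls, and for CD24 siRNA against vehicle the 5 and 5, among protein-coding genes with an adjusted p under 0.05 whose 3 same-numbered differences share the sign of the mean difference; where none pass, they are the 6 with the smallest p. Cd24a and up to 4 members of each list with the smallest p come in addition, as do the passing members of lists that pass camera.

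Same-numbered arrays deviated together from their group means. The correlations of these deviations across genes were 0.377 to 0.732 between arrays of the same number and at most 0.116 between other numbers, and 9 of 9 arrays correlated best with an array of their own number. The titles give the numbers, so the numbers were taken to pair the samples, and a fit with the replicate number as a fixed block was the alternative printed beside results it changes. The first principal component held 40.9% of the variance. The second, 29.7%, set number 1 apart from numbers 2 and 3, which the third (13.2%) parted from each other.

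The fits and camera were tested on simulated data drawn from the real genes' means and spread with 200 changed genes, in 5 draws per fold size, which for 2-fold changes left 7.8 false calls per draw without the block and 16.8 with it. Each fit had its own draws, with deviations shared within a replicate number only in those for the blocked fit. Camera called a list moved by 0.3 log2 units in 20 of 20 draws and made 3 calls among the 21 unmoved lists of those 20 draws, which were drawn without correlation between genes. For the comparisons that share the vehicle arrays, 100 draws of unchanged groups were set against the real vehicle arrays, with the true level drawn around the vehicle mean. Alternatives to the main analysis were the replicate block, leaving out each array, no filter or a filter at the 75th percentile (8.07), quantile normalization, centring on array medians, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, fits of only the 2 groups compared, a 2-fold threshold, an adjusted p of 0.01 and an estimated correlation for camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

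Some choices followed the data. Fits that combine the block with fewer arrays or with an estimated correlation, and the second Cd24a probe set, were added later. The test of a smaller general response on the members of the inflammatory list replaced an earlier test on that list's median change (-0.13, SD 0.16 between numbers), which had decided nothing. The test of scrambled replicate 1 on S phase genes first ran without the block (median -0.02), and was replaced because the number of a missing array then enters the difference. The cross-fitted ratio in the simulations was added later too. A blocked fit of numbers 1 and 2 alone was run once and set aside, because it picks pairs by their Cd24a level; it called no gene between CD24 siRNA and scrambled siRNA and its values are not reported. The single genes followed across alternatives in that comparison were limited to the 6 with the smallest p and the leading members of the 3 lists that passed, after a wider set had been run in which further genes, none of them called, changed sign.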

Results

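Gene expression was measured in 3T3-L1 cells, a mouse fibroblast line that can be induced to become adipocytes, on 9 single-colour oligonucleotide arrays. Confluent, growth-arrested pre-adipocytes had been given IBMX, a phosphodiesterase inhibitor that raises cAMP, together with dexamethasone (Dex), a synthetic glucocorticoid, for 6 h at 0.5 mM and 1 µM. There were 3 groups of 3 arrays: vehicle, IBMX/Dex after a scrambled control siRNA, and IBMX/Dex after an siRNA against CD24, a small glycosylated surface protein encoded in the mouse by Cd24a. The labels do not say whether the vehicle cells received an siRNA. If they did not, the changes against vehicle that are given below for IBMX/Dex may include effects of transfection. They also do not say that the replicates were separate cultures, so the p-values measure the spread between these samples. Each array gave values for 41345 probe sets, with array medians between 6.47 and 6.56 on the log2 scale. Within a group the arrays correlated at r between 0.963 and 0.990 across probe sets, which are not independent replicates. The number of arrays limits the precision: in the fit across 12630 genes the median 95% interval of a difference extended 0.34 log2 units, or 1.27-fold, to either side.

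The first question was whether the siRNA had lowered its target. Cd24a was measured by 2 probe sets. On the brighter one (probe set 17233022) its level was 9.43 ± 0.52 (SD, n = 3) with vehicle, 11.58 ± 0.34 (SD, n = 3) with scrambled siRNA and IBMX/Dex, and 10.67 ± 0.90 (SD, n = 3) with CD24 siRNA and IBMX/Dex, in log2 units. With IBMX/Dex and the scrambled siRNA Cd24a was thus 4.42-fold above vehicle (log2 fold change 2.15 ± 0.43 SE, limma adjusted p = 0.0204), and all 3 same-numbered differences were positive. The CD24 siRNA arrays of replicates 1 and 2 stood at 10.15 and 10.16, which is 2.06-fold and 2.96-fold below their same-numbered scrambled arrays at 11.19 and 11.73. The array labelled CD24 siRNA replicate 3 stood at 11.72, beside 11.81 on the scrambled array of that number, a difference of -0.10. The second probe set (17240606) gave differences of -2.05, -2.03 and -0.18 for the same 3 pairs. With every array kept, the group difference from scrambled siRNA was -0.90 ± 0.43 SE on the brighter probe set. It did not pass in limma (adjusted p = 1, and adjusted p = 1 with the replicate number as a block). That adjustment runs over all genes tested, while Cd24a was the target fixed beforehand. Its unadjusted limma p was 0.0638, and 0.0118 with the block. On the second probe set the group difference was -1.42 (unadjusted p = 0.0205, and 0.00296 with the block). The label of the array named CD24 siRNA replicate 3 was therefore not borne out by its target gene, and every difference involving CD24 siRNA below includes that array unless said otherwise. Cd24a with CD24 siRNA and IBMX/Dex was 2.37-fold above vehicle (adjusted p = 0.124, and adjusted p = 0.0143 with the replicate block). The second probe set gave 2.05-fold (adjusted p = 0.274, and adjusted p = 0.0673 with the block). The same-numbered differences from vehicle were 1.27, 0.24 and 2.23 on the brighter probe set and 0.44, 0.27 and 2.39 on the second, so the value rests largely on the array labelled CD24 siRNA replicate 3.

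**Figure D1:**
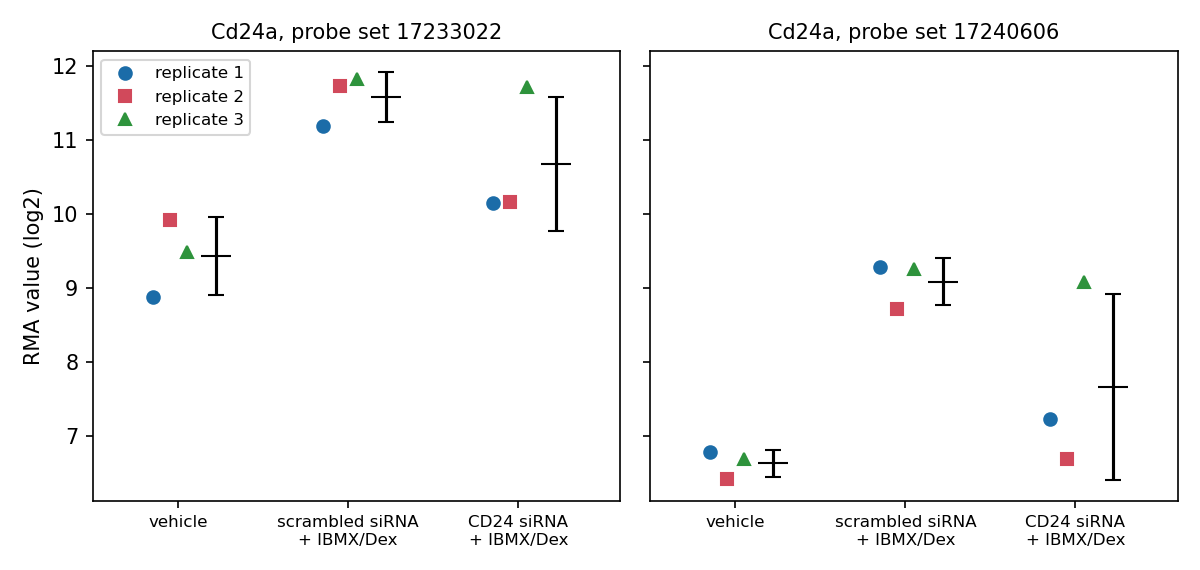
Log2 RMA value of Cd24a (y axis) on each of the 9 arrays by group (x axis), for the brighter probe set on the left and the dimmer one on the right; symbols mark the replicate number, and the bars give the mean and SD of 3 arrays. The array labelled CD24 siRNA replicate 3 lies at 11.72 and 9.08, next to the scrambled arrays, while CD24 siRNA replicates 1 and 2 lie at 10.15 and 10.16 on the left and at 7.22 and 6.68 on the right.

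The next comparison set cells with the scrambled siRNA and 6 h of IBMX/Dex against vehicle. The largest rises were those of Prg4, a secreted lubricating proteoglycan (21.6-fold, log2 fold change 4.43 ± 0.17 SE, adjusted p = 8.36e-06), Ramp3, an accessory protein of calcitonin-family receptors (12.6-fold), and Rgs2, a regulator of G protein signalling (10.8-fold). The orphan nuclear receptor genes Nr4a3 and Nr4a1 rose 10.1-fold and 9.71-fold, and the tolloid-like protease gene Tll1 rose 9.17-fold. Id2, an inhibitor of helix-loop-helix transcription factors, rose 8.30-fold (adjusted p = 0.0342), and Uap1, which makes UDP-N-acetylglucosamine, rose 7.18-fold. Ctla2a, Pi15, Fgl2 and the cytokine gene Il11 rose between 6.16-fold and 6.53-fold. The largest falls were those of Rab7b, a small GTPase gene (6.11-fold lower, log2 fold change -2.61 ± 0.17 SE, adjusted p = 8.48e-05), the aggrecan-degrading protease gene Adamts5 (5.47-fold), Serpinb8 (5.26-fold), F3, which encodes tissue factor (4.98-fold), Tlr3, a receptor for double-stranded RNA (4.74-fold), and the hormone gene Fgf23 (4.49-fold, adjusted p = 0.0397). Cdc42ep3 (4.38-fold) and the oxysterol hydroxylase gene Cyp7b1 (4.31-fold) fell as well. So did 4 genes of G protein-coupled receptors, Grpr (4.32-fold), Calcrl (4.24-fold), Npy1r (4.21-fold) and Gpr176 (3.99-fold). Calcrl encodes a receptor that pairs with the Ramp3 product, which changed in the opposite direction.

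Of the 12630 genes tested, 876 passed an adjusted p of 0.05 in limma, 421 higher and 455 lower with IBMX/Dex, and 268 of them had changed at least 2-fold (146 higher, 122 lower). With the replicate number as a block the count was 2942 (1503 higher, 1439 lower). Leaving out scrambled replicate 1, 2 or 3, vehicle replicate 3 or CD24 siRNA replicate 2, which shares in the estimate of the spread, gave 496, 472, 313, 485 and 581 genes. Of the genes named above, Id2 and Fgf23 no longer passed without any 1 of the scrambled or CD24 siRNA arrays, Id2 also without vehicle replicate 2, Tlr3 without scrambled replicate 2 or 3, and Cyp7b1 without scrambled replicate 3 or vehicle replicate 3. These fits had no block, so that the number of the array left out is unpaired and enters the difference. The size of some changes also rested on 1 array. The log2 fold change of Id2, 3.05 with all arrays, was 2.04 without vehicle replicate 3 and 3.78 without vehicle replicate 1, and that of Fgf23 went from -2.17 to -1.44 without vehicle replicate 2.

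The gene lists fixed beforehand were compared next. Of 19 tested cAMP and CREB targets 11 rose and none fell (13 rose and 1 fell adjusted over the list alone), and the list median was 1.01 log2 units higher (camera adjusted p = 2.52e-09, and adjusted p = 0.126 with an estimated correlation between genes). Besides Rgs2 and the Nr4a genes, among them Nr4a2 (2.79-fold), these were the transcription factor gene Nfil3 (3.31-fold), the kinase gene Sik1 (2.21-fold), the cAMP phosphodiesterase genes Pde4b (2.02-fold), Pde4d (2.07-fold) and Pde10a (2.61-fold), Gem and Crem. Of 19 glucocorticoid receptor targets 7 rose and 1 fell (11 rose and 1 fell adjusted over the list alone; median 0.68, camera adjusted p = 2.23e-06, and adjusted p = 0.328 with an estimated correlation). Glul, which encodes glutamine synthetase, rose 4.99-fold, the phosphatase gene Dusp1 4.89-fold, the immunophilin gene Fkbp5 3.58-fold and Tsc22d3 2.19-fold, whereas Angptl4, an inhibitor of lipoprotein lipase, fell 2.48-fold. All 15 cholesterol synthesis genes had negative differences and 7 of them fell (11 adjusted over the list alone; median -0.57, camera adjusted p = 1.72e-08, and adjusted p = 0.328 with an estimated correlation). The 7 were Fdft1 (2.33-fold lower), Fdps (2.17-fold), Insig1 (1.96-fold), Msmo1 (1.93-fold), Srebf2 (1.67-fold), Hmgcs1 (1.63-fold) and Mvk (1.49-fold). Insig1 and Srebf2 encode regulators of the pathway rather than its enzymes. Mvk did not pass without any 1 of the scrambled arrays, nor Msmo1 without scrambled replicate 2. None of these 3 lists thus kept its call with an estimated correlation. A rotation test (fry in limma, with the replicate block) asks whether the members changed, without comparing them with other genes. Its p, not adjusted over the lists, was 7.0e-06 for cAMP and CREB targets, 8.9e-06 for glucocorticoid receptor targets and 1.7e-04 for cholesterol synthesis genes. With the replicate block 12 cAMP targets rose and 2 fell, 12 glucocorticoid receptor targets rose and 3 fell, and 12 cholesterol synthesis genes fell.

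A further pair of lists passed camera with few members passing. The median of 18 interferon-stimulated genes was -0.93 (adjusted p = 0.0244, and adjusted p = 0.806 with an estimated correlation), but Ifit2 alone fell (2.64-fold), also adjusted over the list alone. The list did not pass without vehicle replicate 1 (median -0.16, adjusted p = 0.574), scrambled replicate 2 (adjusted p = 0.273) or scrambled replicate 3 (adjusted p = 0.120, and Ifit2 did not pass). The median of 14 genes listed as matrix remodelling proteases, which include the protease inhibitor gene Timp2, was -0.32 (adjusted p = 0.0245, and adjusted p = 0.649 with an estimated correlation), with Adamts5 the gene that fell, and adjusted over the list alone 3 fell. It did not pass without scrambled replicate 2 (adjusted p = 0.214), vehicle replicate 1 (adjusted p = 0.112) or vehicle replicate 3 (adjusted p = 0.0562). Where the block kept the numbers paired, the interferon list was lost without scrambled replicate 2 alone (adjusted p = 0.0503) and the proteases in no case. With the replicate block 4 interferon-stimulated genes fell, while 3 of the proteases fell and 1 rose. The rotation test gave an unadjusted p of 0.143 for the interferon list and 1.2e-04 for the proteases.

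The other lists did not pass camera (adjusted p between 0.0997 and 0.981), although some members did. Of 18 inflammatory and NF-kB targets 6 fell and none rose (6 fell and 2 rose adjusted over the list alone; median -0.13, adjusted p = 0.0997), among them the chemokine genes Ccl2 (2.56-fold lower) and Ccl7 (2.29-fold) and the adhesion molecule gene Vcam1 (1.88-fold). Of 16 pro-adipogenic regulators 2 rose, Klf5 (2.23-fold) and Fosl2 (1.85-fold), and 4 fell, among them Nr3c1, the gene of the glucocorticoid receptor (2.27-fold lower), Stat5a (1.95-fold) and Stat5b (2.20-fold). The insulin and IGF signalling genes split as well: Irs2 (2.86-fold) and Pik3r1 (2.07-fold) rose, while Irs1 (2.88-fold) and Rhoq (2.05-fold) fell, of 15 tested. Of 17 anti-adipogenic regulators Id2 rose and Klf3 fell (1.47-fold). The lipid synthesis genes Fasn (1.62-fold) and Scd1 (1.87-fold) rose and Agpat2 fell (1.36-fold) among 13 mature adipocyte genes. Of 14 circadian clock genes Per1 (2.89-fold), Cry2 (1.98-fold) and Cry1 rose and Nr1d1 (1.69-fold) fell. Rrm2 rose 2.59-fold among 18 S phase genes, and Dnajb9 rose 1.72-fold among 19 genes of the stress and unfolded protein responses. Fas fell 3.15-fold among 13 p53 targets, and among 17 Wnt pathway genes Fzd4 rose (1.53-fold) and Lef1 fell (2.03-fold). No member passed among 19 mitosis genes, 15 glucose uptake and glycolysis genes, 10 CD24 ligands, partners and Src family kinases, 9 reference genes or 19 extracellular matrix and contractile genes. With the block 2 mitosis genes, 2 glycolysis genes and 1 reference gene rose, and 1 gene of the CD24 list fell. The matrix list passed camera with the replicate block (median -0.17, adjusted p = 0.118 without it, adjusted p = 0.0390 with it, and adjusted p = 0.876 with the block and an estimated correlation), and without scrambled replicate 1 (adjusted p = 0.0350) or vehicle replicate 3 (adjusted p = 0.0320). S phase and mitosis genes passed as higher without scrambled replicate 1 (adjusted p = 0.00908 and 0.0377) or vehicle replicate 2 (adjusted p = 0.0441 and 0.0184), and inflammatory targets as lower without scrambled replicate 1 (adjusted p = 0.0217). With the block, S phase and mitosis genes did so without scrambled replicate 1 (adjusted p = 0.00757 and 0.0114) and mitosis genes without vehicle replicate 3 (adjusted p = 0.0209), while inflammatory targets did not. The matrix list with the block was lost without scrambled replicate 1 (adjusted p = 0.0904), vehicle replicate 1 (adjusted p = 0.198) or vehicle replicate 2 (adjusted p = 0.0703). With all arrays and an estimated correlation the adjusted p of these 4 lists was 0.806 to 0.961. Adjusted over the list alone, 2 anti-adipogenic regulators rose and 2 fell, 4 clock genes rose and 3 fell, and 3 stress response genes rose and 2 fell. On that scale 3 Wnt pathway genes rose and 1 fell, 2 pro-adipogenic regulators rose and 5 fell, 2 insulin and IGF signalling genes rose and 3 fell, and 2 p53 targets fell. For mature adipocyte, S phase and skeletal muscle genes the counts were those over all genes, and for the lists with no passing member they were 0. With the replicate block 2 inflammatory targets rose and 7 fell, and 3 pro-adipogenic regulators rose and 6 fell. Likewise 5 anti-adipogenic regulators rose and 4 fell, 4 Wnt pathway genes rose and 4 fell, 4 stress response genes rose and 4 fell, and 4 S phase genes rose. The block also gave 4 mature adipocyte genes that rose and 1 that fell, 3 and 4 insulin and IGF signalling genes, 4 and 3 clock genes, 1 and 2 p53 targets, and 1 and 4 matrix genes. The calls of Agpat2, Scd1, Fasn, Fzd4, Cry1, Dnajb9, Klf3, Irs1, Fas and Lef1 were each lost on leaving out any of several single arrays. Ccl2 did not pass without scrambled replicate 3 or vehicle replicate 3, Des without scrambled replicate 3 or vehicle replicate 2, Fosl2 without scrambled replicate 3 and Vcam1 without scrambled replicate 2. The medians of the anti-adipogenic, circadian and reference lists were negative and their means positive, and those of the Wnt, stress response and macrophage lists the reverse. Of the markers of other cell types, the brightest of each list had mean log2 values, beside the filter level of 6.51, of 8.61 (Cd14, macrophage), 7.88 (Tnnt2, muscle), 7.44 (Col2a1, chondrocyte), 6.83 (Krt14, epithelial) and 6.75 (Cdh5, endothelial). Of the 5 tested macrophage markers none passed (1 rose and 1 fell with the block), and of the 5 tested skeletal muscle markers Des fell 1.62-fold, while endothelial, epithelial and osteoblast and chondrocyte markers had too few genes above the filter (2, 2 and 3) for a test.

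**Figure D2:**
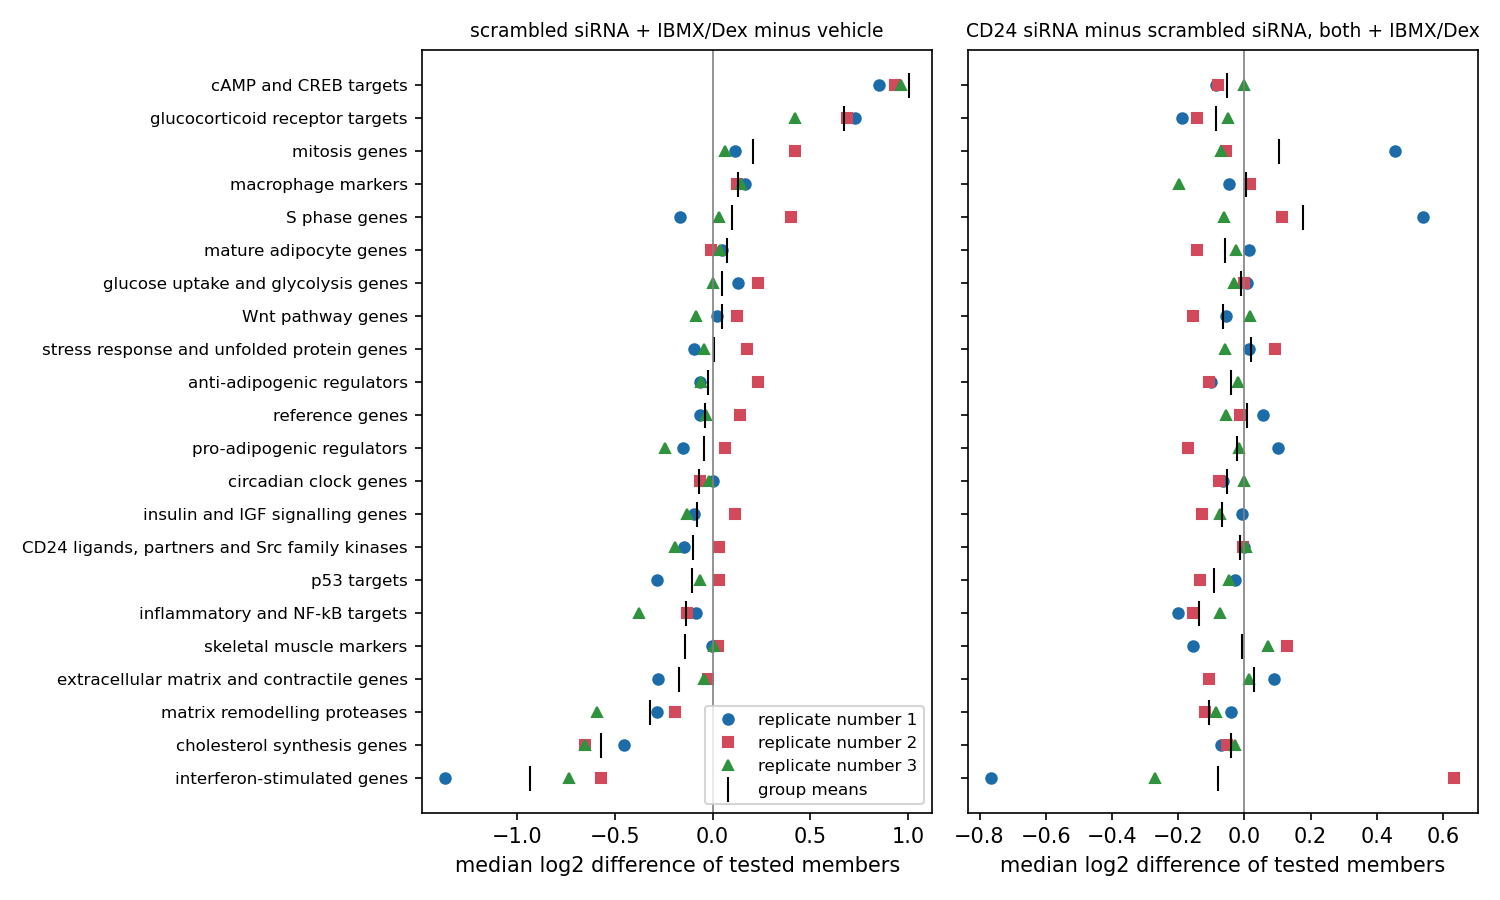
Median log2 difference of each list's tested members (x axis) for the 22 gene lists tested (y axis), for IBMX/Dex with scrambled siRNA minus vehicle on the left and CD24 siRNA minus scrambled siRNA on the right, each panel with its own scale; symbols give the 3 differences between same-numbered arrays and the black tick the median difference of the group means. On the left cAMP and CREB targets lie at 1.01, cholesterol synthesis genes at -0.57 and interferon-stimulated genes at -0.93, and on the right S phase genes lie at 0.54, 0.11 and -0.06 for numbers 1, 2 and 3.

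The response was then measured in the CD24 siRNA arrays against the same vehicle arrays. Prg4 (20.6-fold; log2 fold change 4.37 ± 0.17 SE), Ramp3 (12.4-fold), Rgs2 (10.6-fold), Tll1 (8.87-fold) and Nr4a1 (8.08-fold) rose most. The largest falls were those of F3 (5.68-fold), Fgf23 (5.55-fold), Rab7b (5.20-fold), Adamts5 (5.19-fold) and Cdc42ep3 (5.06-fold). In this comparison 840 genes passed in limma, 369 higher and 471 lower, of which 262 had changed at least 2-fold. With the replicate block 2831 genes passed (1309 higher, 1522 lower). Without the array labelled CD24 siRNA replicate 3 the counts were 321, and 1763 with the block. Without CD24 siRNA replicate 1 or 2 or vehicle replicate 3 the unblocked counts were 359, 369 and 458. Fgf23 did not pass without any 1 of the CD24 siRNA arrays, and its log2 fold change went from -2.47 to -1.74 without vehicle replicate 2. Of 19 cAMP and CREB targets 11 rose and 1 fell, of 19 glucocorticoid receptor targets 6 rose and 1 fell, and 7 of 15 cholesterol synthesis genes fell (camera adjusted p = 1.26e-08, 4.74e-05 and 3.50e-09). None of these 3 passed with an estimated correlation (adjusted p = 0.163, 0.392 and 0.392). Matrix remodelling proteases (3 of 14 fell, adjusted p = 0.00484), inflammatory and NF-kB targets (6 of 18 fell, adjusted p = 0.00590), interferon-stimulated genes (1 of 18 fell, adjusted p = 0.00895) and S phase genes (1 of 18 rose, adjusted p = 0.0107) also passed camera. None of the 4 passed with an estimated correlation (adjusted p = 0.392 to 0.825). By number the medians were -1.90, 0.11 and -0.93 for interferon-stimulated genes and 0.42, 0.56 and -0.03 for S phase genes, so that 1 number went the other way in each. Mitosis genes passed with the block (adjusted p = 0.368 without it, adjusted p = 0.00153 with it, and adjusted p = 0.716 with the block and an estimated correlation) although no member passed without it. Adjusted over the list alone, 12 cAMP and CREB targets rose and 1 fell, 11 glucocorticoid receptor targets rose and 2 fell, and 12 cholesterol synthesis genes, 3 proteases, 8 inflammatory targets and 1 interferon-stimulated gene fell and 1 S phase gene rose. With the block 12 cAMP and CREB targets rose and 2 fell, 2 inflammatory targets rose and 9 fell, and 5 mitosis genes rose. It also gave 11 glucocorticoid receptor targets that rose and 3 that fell, while 12 cholesterol synthesis genes, 5 interferon-stimulated genes and 5 proteases fell, and 1 protease and 7 S phase genes rose. The median and mean differed in sign for anti-adipogenic, circadian, mature adipocyte, reference, Wnt and macrophage lists here, none of which passed. Interferon-stimulated genes did not pass without vehicle replicate 1 (adjusted p = 0.419) or the array labelled CD24 siRNA replicate 3 (adjusted p = 0.0592), nor S phase genes without vehicle replicate 1 (adjusted p = 0.194) or CD24 siRNA replicate 2 (adjusted p = 0.345). With the block S phase genes passed without any 1 array, and the interferon-stimulated, inflammatory and mitosis lists were lost without CD24 siRNA replicate 1 (adjusted p = 0.0584, 0.0643 and 0.102).

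The responses with either siRNA were then set against each other. There were 715 genes called with both siRNAs in the same direction, 332 higher and 383 lower, and none in opposite directions. Independent lists of these lengths would share 12.3 higher and 17.0 lower genes, and simulated unchanged groups against the same vehicle arrays shared 0 in each of 100 draws. The log2 fold changes of the 12630 genes correlated at 0.958 across genes, which are not independent replicates, against 0.500 in the simulated unchanged groups, and their covariance was 0.149 against 0.008. The simulated groups had no response, so their overlap of 0 does not measure what shared vehicle error adds among responding genes. Their correlation of 0.500 is set by how they were drawn. The vehicle group is too small to be split, so part of the overlap may come from the shared vehicle arrays.

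**Figure D3:**
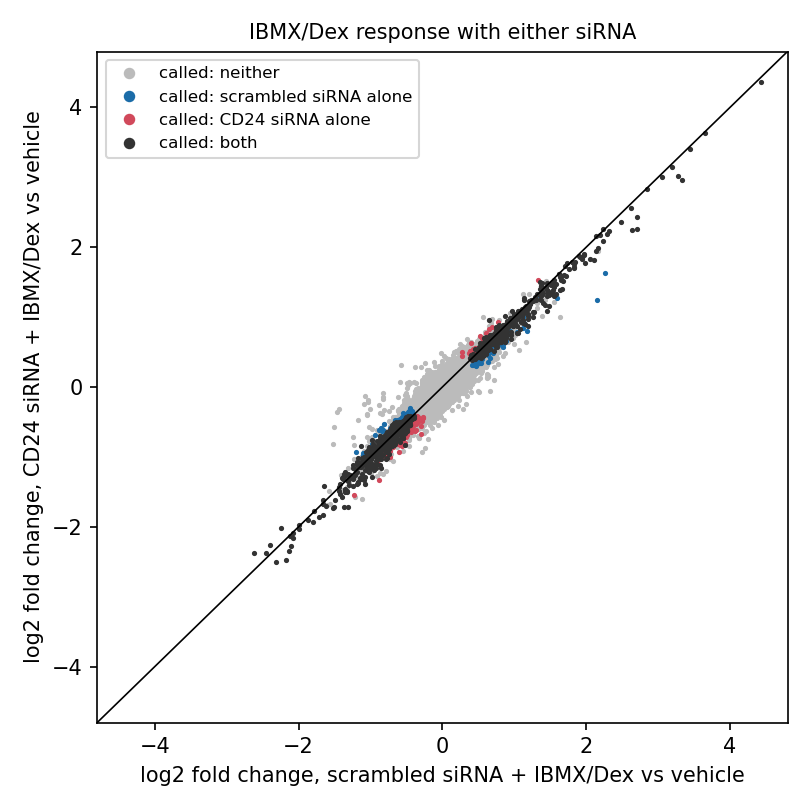
Log2 fold change against vehicle of each of 12630 genes with scrambled siRNA and IBMX/Dex (x axis) and with CD24 siRNA and IBMX/Dex (y axis); each point is a gene, coloured by the comparisons in which it passed an adjusted p of 0.05, and the line marks equal changes. The 715 genes called in both lie along the line.

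Over the 876 genes called with scrambled siRNA, the median ratio of the change with CD24 siRNA to that with scrambled siRNA was 0.963, with quartiles at 0.883 and 1.03, and 0.959, 0.945 and 0.989 within numbers 1, 2 and 3. Because those genes were chosen on the scrambled arrays, simulated groups with equal true responses gave a mean ratio of 0.964 (0.953 to 0.980 in 100 draws). When genes were chosen without the scrambled array used in the ratio, the mean ratio was 1.04, and the same simulations gave 1.04 (1.02 to 1.06). Among the 876 genes, 576 (65.8%) lay nearer to vehicle with CD24 siRNA, against a mean of 60.3% and at most 64.6% in the simulations, which draw genes independently and so understate the spread of this share.

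The central comparison asked what CD24 siRNA changed within IBMX/Dex. No gene passed in limma. Unadjusted p was under 0.05 for 30 genes where 631.5 would have it by chance, and with the replicate block no gene passed and 219 had an unadjusted p under 0.05. The spread in the unblocked fit includes the deviations that same-numbered arrays share, which cancel in this difference. Counts this far below 631.5 mean that the p-values ran too large, so they are not evidence that nothing changed. The 6 protein-coding genes with the smallest p, none of which passed, were 2 olfactory receptor genes, Olfr1362 (log2 difference 0.58 ± 0.16 SE) and Olfr282 (0.31 ± 0.11 SE), the zinc finger gene Zfp326 (-0.36 ± 0.11 SE), Unc93a (0.36 ± 0.12 SE), the lactate dehydrogenase gene Ldhb (-0.28 ± 0.11 SE) and Skint7 (0.38 ± 0.14 SE), all with an adjusted p = 1. Of these, Skint7 and Unc93a lay near the filter level of 6.51 (means 6.19 and 6.32 with scrambled siRNA, 6.57 and 6.68 with CD24 siRNA). In number 3, where Cd24a was not lowered, the differences were the largest of the 3 numbers for Olfr1362 (0.83), Skint7 (0.64) and Ldhb (-0.39). That of Zfp326 was the smallest there (-0.19), and those of Unc93a (0.32) and Olfr282 (0.24) lay between. Without the array labelled CD24 siRNA replicate 3 no gene passed either, with or without the block, and 54 and 264 genes had an unadjusted p under 0.05. For 12111 genes (95.9%) the 95% interval of the difference lay within 2-fold in either direction. Simulated data had 200 genes changed on all 3 CD24 siRNA arrays. The unblocked fit recovered 81.3% of genes changed 2-fold and 0.7% of those changed 1.5-fold. The blocked fit recovered 77.1% of genes changed 1.5-fold, in separate draws with a smaller spread and with deviations shared within a number. The draws for the unblocked fit had no shared deviations, unlike the real arrays. How many 1.5-fold changes the unblocked fit misses on the real arrays was therefore not measured. Cd24a itself was lowered in numbers 1 and 2 and not in number 3. A change that follows Cd24a would therefore be smaller in the mean of the 3 arrays and more spread. Neither the simulation nor the intervals cover that case, so 2-fold changes on the arrays with lowered Cd24a are not excluded.

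Camera nonetheless called 3 lists between CD24 siRNA and scrambled siRNA, none with a member that passed or would pass adjusted over the list alone. All 18 S phase genes had positive differences (median 0.18, adjusted p = 0.000194, and adjusted p = 0.680 with an estimated correlation), led by Ccne1 (0.28 ± 0.23 SE), Mcm2 (0.21 ± 0.23 SE), Mcm3 (0.30 ± 0.33 SE) and Cdc6 (0.29 ± 0.33 SE), genes of entry into and start of DNA replication. All 18 inflammatory and NF-kB targets had negative differences (median -0.14, adjusted p = 0.000441, and adjusted p = 0.581 with an estimated correlation), led by Birc3 (-0.25 ± 0.16 SE), Cxcl1 (-0.39 ± 0.28 SE), Il6 (-0.64 ± 0.55 SE) and Csf3 (-0.20 ± 0.18 SE). Of 19 glucocorticoid receptor targets 18 had negative differences (median -0.09, adjusted p = 0.00643, and adjusted p = 0.581 with an estimated correlation), led by Angptl4 (-0.41 ± 0.20 SE), Cebpd (-0.37 ± 0.24 SE), Klf9 (-0.23 ± 0.23 SE) and Sgk1 (-0.18 ± 0.22 SE). The block added mitosis genes (median 0.10, adjusted p = 0.000104, against adjusted p = 0.181 without it) and insulin and IGF signalling genes (median -0.07, adjusted p = 0.0348, against adjusted p = 0.153 without it). With the block and an estimated correlation neither passed (adjusted p = 0.561 and adjusted p = 0.451). In the rotation test with the block the unadjusted p was 0.336 for S phase genes, 0.0943 for inflammatory targets and 0.0253 for glucocorticoid receptor targets. It was 0.494 for mitosis genes and 0.0502 for insulin and IGF signalling genes. The S phase difference was 0.54, 0.11 and -0.06 in numbers 1, 2 and 3. Without the block, which leaves the number of a missing array unpaired, it did not pass without scrambled replicate 1 (median -0.02, adjusted p = 0.889), scrambled replicate 3 (adjusted p = 0.0792) or CD24 siRNA replicate 2 (median -0.03, adjusted p = 0.855). Without scrambled replicate 1 the inflammatory list (adjusted p = 0.434) and the glucocorticoid receptor targets (adjusted p = 0.464) did not pass either, nor did the latter without scrambled replicate 3 (adjusted p = 0.217) or CD24 siRNA replicate 2 (adjusted p = 0.809). With the block these 3 lists were lost without scrambled replicate 1 (adjusted p = 0.143 each, S phase median 0.04), and the glucocorticoid receptor targets also without CD24 siRNA replicate 2 (adjusted p = 0.0963). Mitosis genes, by number 0.45, -0.06 and -0.07, were then lost without scrambled replicate 1 (adjusted p = 0.207) or CD24 siRNA replicate 1 (adjusted p = 0.898). Insulin and IGF signalling genes were lost without any 1 of scrambled replicates 1 and 2 and CD24 siRNA replicates 1 and 2 (lowest adjusted p = 0.0762). With all arrays and no block, none of the remaining 19 lists tested passed in this comparison, the cAMP and CREB targets (median -0.05, adjusted p = 0.0916) and the cholesterol synthesis genes (median -0.04, adjusted p = 0.173) among them. Without the array labelled CD24 siRNA replicate 3, 9 lists passed at the preset correlation, and 7 with the block. An estimated correlation, at which no list passed with all arrays, was not run for that exclusion.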

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

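The tests of the Cd24a array, of the list differences by replicate number or by member and of scrambled replicate 1 were chosen after those results had been seen; the counts over other splits of the arrays were planned.

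Cd24a on the array labelled CD24 siRNA replicate 3 is the pattern most in need of a closer look. A swap with the scrambled array of that number would leave a low value there, but that array lay 0.36 log2 units above the mean of the other scrambled arrays. An array of number 1 or 2 in this place is argued against by the deviations from the group means, which correlated with the other number 3 arrays at 0.377 or more and with arrays of other numbers at 0.106 or less. A fault of 1 probe set is argued against by the second probe set, which differed by -0.18 in number 3 and by -2.05 and -2.03 in numbers 1 and 2. A culture of this set in which Cd24a was not lowered and a scrambled siRNA culture carrying this label predict the same level (difference -0.10), so these cannot be told apart.

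The difference between the responses to IBMX/Dex with either siRNA was itself tested by comparing CD24 siRNA with scrambled siRNA, and 3 lists passed camera at the preset correlation, none with a member that passed. S phase genes were higher with CD24 siRNA (camera adjusted p = 0.000194, and adjusted p = 0.680 with an estimated correlation), at 0.54, 0.11 and -0.06 in numbers 1, 2 and 3. The array labelled scrambled replicate 1 may account for it, since with the replicate block the median was 0.0418 without that array (adjusted p = 0.143), but it was 0.06 without CD24 siRNA replicate 1, so which array of number 1 sets it apart cannot be told. Loss of Cd24a would need a higher list in numbers 1 and 2 than in number 3, which holds (0.11 in number 2), but 3 pairs cannot decide it.

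Inflammatory and NF-kB targets were lower with CD24 siRNA (adjusted p = 0.000441, and adjusted p = 0.581 with an estimated correlation), by medians of -0.20, -0.15 and -0.074 in numbers 1, 2 and 3. The smaller difference in number 3, whose Cd24a was not lowered, is the order that loss of Cd24a would give, but 7 of the 22 lists lay lower in that order, 5 of which did not pass, so it does not mark this list. A smaller response to IBMX/Dex in general would raise the 10 members lower with scrambled siRNA and IBMX/Dex than with vehicle. Their median difference was -0.11 (SD 0.070 between numbers), at -0.21, -0.10 and -0.07 in numbers 1, 2 and 3. The 7 members above vehicle with both siRNAs lay beyond what the ratio of 0.963 over all called genes gives by -0.14 (SD 0.026). Their medians were -0.19, -0.18 and -0.14 in numbers 1, 2 and 3, so that number 3 stood close to the others. All 18 members were known to have negative differences when this test was written, so the signs were fixed in advance. Simulated equal responses gave a ratio of 0.964, so that ratio showed no smaller response to test. No conclusion is therefore drawn. This list too did not pass with the block without the array labelled scrambled replicate 1 (median -0.11, adjusted p = 0.143).

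Glucocorticoid receptor targets were lower with CD24 siRNA as well (median -0.09, adjusted p = 0.00643, and adjusted p = 0.581 with an estimated correlation). The medians were -0.19, -0.14 and -0.05 in numbers 1, 2 and 3. No member passed, and with the block the list did not pass without scrambled replicate 1 (adjusted p = 0.143) or CD24 siRNA replicate 2 (adjusted p = 0.0963).

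The numbers of genes called can be set against other splits of the same 6 arrays, of which there are 10, too few for a share under 0.05. IBMX/Dex with scrambled siRNA gave 876 genes and the highest other split 0, so that 1 of 10 splits, the real one, gave as many; IBMX/Dex with CD24 siRNA gave 840 and the highest other split 0, again 1 of 10. CD24 siRNA against scrambled siRNA gave 0, as did all 10 splits. Among the 4 splits that part all 3 pairs, with the replicate block, the real ones gave 2942, 2831 and 0 genes and the highest others 0. For the lists the picture differs. With scrambled siRNA and IBMX/Dex 5 lists passed camera and the highest other split gave 7, with as many in 5 of 10 splits. With CD24 siRNA and IBMX/Dex 7 passed and the highest other gave 7, with as many in 2 of 10. Between the 2 siRNAs 3 passed and the highest other gave 7, with as many in 6 of 10. Splits of the CD24 siRNA and scrambled arrays that part only 1 pair, and so set whole numbers against each other, gave up to 1109 genes with an unadjusted p under 0.05. Those that part all 3 pairs gave at most 85, and the real one gave 30. This points to the structure set by the replicate numbers.

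Some probe sets left out of the comparisons also passed for IBMX/Dex with scrambled siRNA, in smaller shares than the 876 of 12630 genes tested. Of 7361 probe sets above the filter with no gene listed, 20 passed in limma (13 higher, 7 lower), and of 1157 with several genes listed, 9 passed (6 higher, 3 lower). With CD24 siRNA and IBMX/Dex 1 and 5 passed. Between CD24 siRNA and scrambled siRNA 0 of either kind passed, and 79 and 1 had an unadjusted p under 0.05.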

How the results depend on the processing

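The fits that combine the replicate block with fewer arrays or an estimated correlation, and the second Cd24a probe set, were chosen after the data had been seen; the other alternatives were planned. No alternative called a gene between CD24 siRNA and scrambled siRNA in limma. The counts at an unadjusted p under 0.05 were 30 in the reported fit, 219 with the block, 241 with array weights and 454 with the block and only those 2 groups. The Cd24a difference stayed negative and short of an adjusted p of 0.05, at -1.42 to -0.64 without single arrays and -1.42 on the second probe set. The counts for IBMX/Dex with scrambled siRNA and with CD24 siRNA, 876 and 840, became 2942 and 2831 with the replicate block, 2405 and 1994 with the block and only the 2 groups compared, and 2924 and 1763 with the block and without the array labelled CD24 siRNA replicate 3. They fell to 389 and 461 with only the 2 groups compared, for which fewer arrays estimate the spread, and to 268 and 262 at 2-fold and 246 and 234 at an adjusted p of 0.01, by construction. Without single arrays they were 313 to 852 and 321 to 857. They were moved over 1.5 times by scrambled replicates 1, 2 and 3, vehicle replicate 3 and CD24 siRNA replicate 2 for the first and by vehicle replicate 3 and each CD24 siRNA array for the second. The overlap of 715 genes became 2383 with the block, 233 at 2-fold and 203 at an adjusted p of 0.01. The ratio of the responses was 0.910 to 0.996 without single arrays and 1.04 when cross-fitted, where simulated equal responses gave 1.04. The lists passing camera, 5, 7 and 3 in the 3 comparisons, were 0, 0 and 0 with an estimated correlation, alone or with the block, and 3 to 9, 5 to 8 and 1 to 9 without single arrays. For IBMX/Dex with scrambled siRNA there were 6 without the filter. Between the siRNAs there were 5 with the block, 5 without the filter and 7 with the block and without the array labelled CD24 siRNA replicate 3. With the block and without each other array there were 0 (scrambled replicate 1), 4 (CD24 siRNA replicates 1 and 2), 5 (vehicle replicate 2), 6 (scrambled replicate 3 and vehicle replicate 1) and 7 (scrambled replicate 2 and vehicle replicate 3). With an estimated correlation, alone or with the block, S phase genes (0.1758), inflammatory targets (-0.1373) and glucocorticoid receptor targets (-0.0862) kept their medians and no longer passed. Without single arrays these medians were -0.0322 to 0.4348, -0.1785 to -0.0637 and -0.1846 to -0.0168, so that S phase genes changed sign where the number of the missing array was unpaired. With the block no median changed sign, and the calls lost were those without scrambled replicate 1 (0.0418, -0.1137 and -0.0585) and, for glucocorticoid receptor targets, without CD24 siRNA replicate 2 (-0.0542). Of 106 genes followed with scrambled siRNA 59 passed, and 22 of those lost their call in some alternative, Agpat2, Cry1, Dnajb9, Fasn, Fzd4, Id2 and Scd1 among them. Signs turned, for genes that did not pass, without single arrays for Birc5 (-0.1185 to 0.5608), Ccnb2 (-1.1321 to 0.1452) and Actb (-0.2688 to 0.0193) with scrambled siRNA, and for Cdc6 (-0.0111 to 0.6067) and Sgk1 (-0.3091 to 0.0918) between the siRNAs, where array weights also turned Sgk1 (0.0374) and Il6 (0.0275). The block changed the call of no list other than those given with the results. Except where a reason is given, the cause was not tested.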

Other observations

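The gene groups here were put together and tested after the gene values had been seen, 4 groups in all, with the genes that prompted each left out of its test; the rules for judging these groups were changed after their values were known, last to require p-values adjusted over the 4.

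Hsph1 and Bag3, a chaperone gene and a co-chaperone gene, rose 3.56-fold and 2.71-fold with IBMX/Dex and scrambled siRNA. The 17 other heat shock genes had a median log2 change of 0.36 (camera adjusted p = 0.0152 over the 4 groups, and adjusted p = 0.111 with an estimated correlation). Of these Dnajb4 rose (1.86-fold) and Hspb8 fell (1.55-fold), and with the replicate block 9 rose and 1 fell. With the estimated correlation and the block the adjusted p was 0.390, so whether the heat shock genes rose as a group stays undecided. Uap1, Gfpt2 and Ugdh, genes of UDP-sugar synthesis, rose 7.18-fold, 5.59-fold and 3.11-fold. The 10 other genes of that group, which includes hyaluronan synthesis, had a median of 0.0924 (camera adjusted p = 0.383), with Gfpt1 higher (1.76-fold) and Nagk lower (1.48-fold), and 4 higher and 2 lower with the block, so that members going both ways leave the group undecided.

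Tlr2, Tlr3, Tlr4 and Sting1, genes of innate immune sensing, fell 2.13-fold, 4.74-fold, 2.47-fold and 2.67-fold with IBMX/Dex and scrambled siRNA. The 16 other receptors and adaptors had a median of -0.2506 (camera adjusted p = 0.0582), with Tlr6 (1.49-fold) and Irak2 (1.59-fold) lower. With the block 7 fell and 3 rose, Nod1, Cgas and Cd14. Between CD24 siRNA and scrambled siRNA, 3 small leucine-rich proteoglycan genes were picked for their values by number, Aspn (-0.82, -0.91 and 0.40 in numbers 1, 2 and 3), Ogn (-1.25, -0.69 and 0.005) and Prelp (-0.87, -0.81 and 0.31). None passed (adjusted p = 1), and the group differences were -0.44 ± 0.73, -0.65 ± 0.81 and -0.45 ± 0.30 SE. The 3 other members tested, Dcn, Bgn and Fmod, did not fall as a set (median 0.0104, camera adjusted p = 0.874). They are too few to speak for the family.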
